A study of Mus musculus and Homo sapiens with 81 samples.

How the data were processed

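Gene expression was measured in 81 poly(A) RNA-seq libraries of cultured cells. The B16 cells carried the guide Ptpn2sg3 or the non-targeting guide Bro3, and the human cells a guide against PTPN2, whose label also reads Ptpn2sg3, or the non-targeting guide Bro4, per the labels. Whether the human cells carried a different guide than the mouse cells is not stated. Treatment lasted 48 h, with 1000 U/mL IFNb, 100 ng/mL IFNg and 10 ng/mL TNFa alone or paired in B16, 100 ng/mL IFNg in the human lines, and vehicle in each (labels' protocols). The labels do not say whether replicates were separate cultures. If they were not, the p-values measure only the spread between these samples, which may be technical. In either case each line had a single guide per genotype. A genotype difference therefore cannot be told apart from other differences between the cells carrying each guide. A375 control vehicle held replicates 2 and 3 only; other groups held 3 libraries (B16, A375, MelJuSo) or 2 (A549, HT29). HT29 control IFNg replicate 1 carries a lung cell type label beside its HT29 cell line label and was grouped by title and cell line.

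The deposited values are raw read counts per gene, per the submitters' processing notes: bcl2fastq 2.17.1.14, Trimmomatic 0.33, Bowtie2 2.2.4 and HTSeq 0.6.1p1 on the builds mm10 and hg19, with DESeq2 listed for their tests. The annotation, the strand setting of the counting and the DESeq2 version are not given in the sources used here. How reads of overlapping genes such as Psmb9 and Tap1 were assigned is therefore uncertain, as are counts of near-identical paralogs. All values were whole numbers, 23336 genes in mouse and 23227 in human, and every library column was matched to its labels. Reads were not used here.

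Counts were analysed per line with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, robust dispersions, 1 mean per group, and the quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes. Tested were 11726 genes in B16 (3498860 to 6432517 counts per library), 13410 in A375 (5323668 to 7951961), 13172 in A549 (6096437 to 8253298), 12555 in HT29 (6848609 to 9605776) and 12271 in MelJuSo (4191317 to 9216731), which held at least 99.88% of the counts. The common biological coefficient of variation was 0.0521 in B16, 0.0201 in A375, 0.0223 in A549, 0.0266 in HT29 and 0.0267 in MelJuSo. Contrasts were each cytokine against vehicle in control cells, Ptpn2-null against control under each treatment, the interaction of both, in B16 the departure from additive log2 effects of paired cytokines, and in the human lines an F test of whether the genotype effect under IFNg differed. B16 responses share their vehicle libraries, so no overlaps between them were computed.

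Gene names in the text follow a rule fixed before the data were examined, as were the contrasts, lists and most alternatives: Ptpn2, a fixed set of 21 genes, up to 10 genes per direction with the largest change among called genes with a mean log2 CPM of at least 1 and (for comparisons of 2 groups) no overlap between groups, and up to 4 called members of each list. Beyond the 4 genes of the TNFa interaction, genes whose call ended in 3 or more of the fits with a library left out or another setting were left out of the text, a choice made after the data were seen, and results of a few further genes are not reported here. The 16 lists covered MHC class I and class II presentation, chemokines, antiviral interferon-stimulated genes, GBP, IRG and other IFNg-inducible genes, the JAK-STAT pathway, NF-kB targets, cell death, T cell ligands, proliferation, melanocyte differentiation, stress and unfolded protein response, and markers of leukocytes, fibroblasts, epithelium and colon epithelium. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation beside it; list counts are members with an adjusted p under 0.05 over all genes and adjusted over the list alone. Folds against groups with 0 counts are lower bounds against a floor of 3 counts over the group, and groups with 1 to 3 counts give a ratio with a 95% exact binomial counting interval, which covers counting error only; interactions of such genes are not printed.

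Alternatives were DESeq2's size factors (RLE), no filter, DESeq2 1.42.0 (genes it gives no adjusted p are left out), a replicate block, only the compared groups in the fit, and leaving out each library. Removal of each B16 library's trend on transcript length (a spline on log2 length from GENCODE M21) and leaving out 5 B16 libraries were added after the data were seen; the removal was revised once, to a robust and centred fit, after its first results. No human reference was used. On simulated data with 200 changed genes, edgeR recovered 185 with 6 false calls for the B16 genotype contrast under IFNg (79.1% of 1.5-fold and 98.5% of 2-fold changes), 170 with 5 false calls for the interaction, and 188 with 13 false calls (6.47% of calls) in A549 with 2 libraries per group. In A549 DESeq2 recovered 164 with 0 false calls, and 58.2% of 1.5-fold changes against 83.6% with edgeR. With a length trend added to the TNFa contrast edgeR made 1555 false calls, and 12 with the trend removed. The trend was added and removed on the same transcript lengths, so its removal was bound to succeed. The simulated groups also shared 1 spread per gene and held no libraries that stand apart. These figures may therefore not hold for groups of unequal spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.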

Results

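The deposited counts covered 81 libraries of cells carrying either a control guide or a guide against Ptpn2 (PTPN2 in human cells), a phosphatase gene whose product acts on the kinases and STAT factors of interferon signalling. The label of the guide in human cells is that of the mouse guide. Ptpn2-null is the genotype as labelled, and protein loss was not measured. With a single guide per genotype in each line, genotype differences may include other differences between the cells carrying each guide. Mouse B16 melanoma cells were given vehicle, IFNb, IFNg, TNFa or a pair of these cytokines for 48 h, in 14 groups of 3 libraries. Human A375 and MelJuSo (melanoma), A549 (lung) and HT29 (colon) cells were given vehicle or IFNg, in 16 groups of 2 or 3 libraries. The questions were how each cytokine changed gene expression in control cells, how cells of the 2 genotypes differed under each treatment, and whether that difference depended on the cytokine. Gene values are log2 fold changes ± SE from edgeR's quasi-likelihood test unless another unit is given. Calls have a Benjamini-Hochberg adjusted p under 0.05. Each SE is the absolute log2 fold change divided by the square root of the test's F. For large changes from few counts this value can be smaller than the counting error, so it overstates the precision there. Gene lists were fixed before the data were examined, and their tests are camera with a preset correlation of 0.01. With an estimated correlation the adjusted p was often far larger, and it is printed only for some lists, so very small values may overstate the evidence. List counts are members called over all genes, followed in brackets by those called when adjusted over the list alone.

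Ptpn2 itself was measured first. In B16, control libraries held 44.7 to 61.9 CPM (counts scaled to library size) of Ptpn2 and Ptpn2-null libraries 8.23 to 16.4, with no overlap under any treatment. The gene lies on chromosome 18 at 67665511 to 67724595, minus strand (GRCm38, GENCODE M21). The genotype effect was -2.35±0.12 under vehicle, -2.20±0.12 under IFNb, -2.28±0.11 under IFNg, -1.97±0.11 under TNFa, -1.98±0.11 under IFNb with IFNg, -2.48±0.11 under IFNb with TNFa and -2.00±0.10 under IFNg with TNFa. Under vehicle and IFNg, PTPN2 was lower in the Ptpn2-null libraries of A549 (-0.99±0.13 and -0.84±0.12), HT29 (-0.82±0.11 and -0.57±0.10) and MelJuSo (-1.18±0.15 and -0.45±0.13). In A375 the vehicle libraries went against their labels: the 3 libraries labelled Ptpn2-null held 24.1, 25.1 and 24.2 CPM and the 2 libraries labelled control 11.9 and 12.1 CPM (1.03±0.13, adjusted p = 3.0e-11). Under IFNg the A375 libraries labelled control held 22.8, 19.2 and 17.2 CPM and those labelled Ptpn2-null 11.3, 12.7 and 13.6 CPM (-0.66±0.12).

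**Figure D1:**
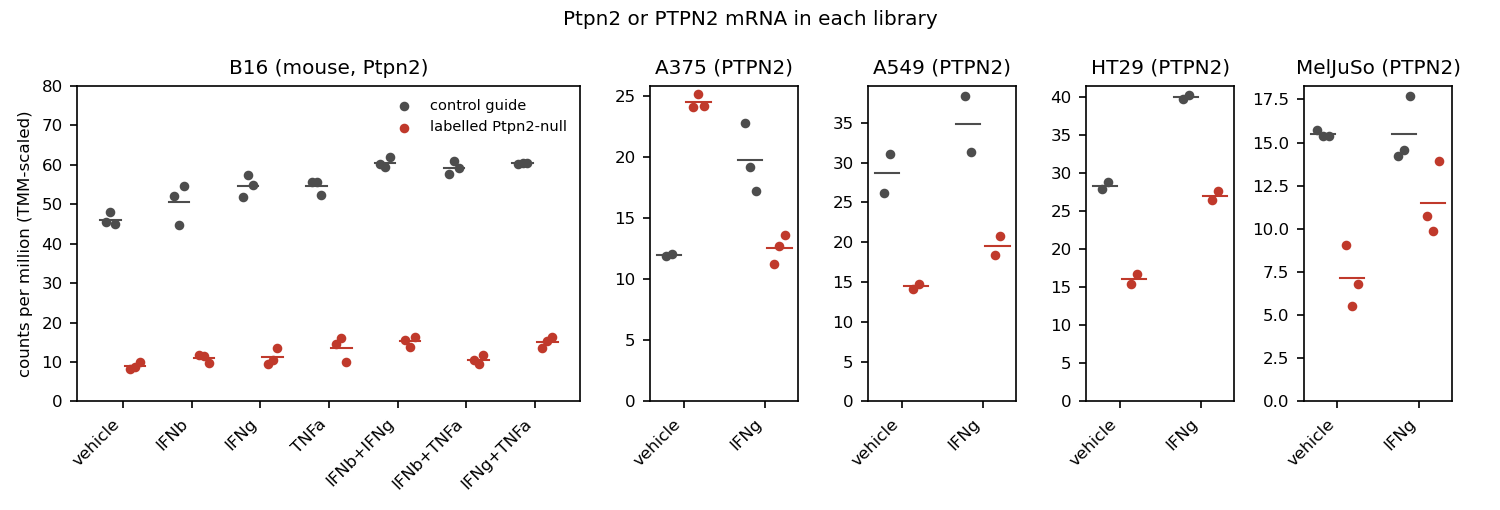
Ptpn2 or PTPN2 in each library (points, CPM after TMM scaling) by treatment, with group means as lines and genotype as labelled by colour. The B16 genotypes are separate under every treatment, while the A375 vehicle libraries labelled Ptpn2-null (24.1 to 25.1 CPM) lie above those labelled control (11.9 and 12.1 CPM).

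IFNb raised the antiviral program of control B16 cells. Transcripts of interferon-induced proteins rose: Oas2 was at least 504-fold higher than a floor of 3 counts, with Irf7 (the factor that amplifies type I interferon signalling) 8.76±0.16, Usp18 8.18±0.15, Isg15 6.49±0.21 and Ifit1 5.59±0.12 (n = 3 per group). The antigen presentation genes B2m 2.73±0.05 (994±36.4 against 150±2.73 CPM) and Tap1 2.92±0.09, the signalling gene Irf9 4.20±0.11, Igtp 6.97±0.18, Lgals9 3.26±0.07, Cxcl10 2.12±0.08 and Cd274 (PD-L1) 1.18±0.13 also rose. The largest falls were in Slc16a3 -1.84±0.20, Kbtbd11 -1.75±0.25, Relb -1.46±0.16 and Bnip3 -1.20±0.17. Antiviral interferon-stimulated genes rose in 25 of 25 (25), MHC class I genes in 14 of 16 (16), and melanocyte genes fell in 15 of 17 (15, adjusted p = 2.5e-07). Dct changed by -0.57±0.04. 3578 of 11726 genes were called, 1991 higher and 1587 lower, 224 and 43 of them at least 2-fold. Mki67 was not called (-0.02±0.06, adjusted p = 0.87), and fold changes rose with transcript length across genes (rho = 0.296).

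IFNg gave a broader response in control B16 cells, which included guanylate-binding and immunity-related GTPases. Iigp1 was at least 16430-fold, Gbp4 at least 8770-fold and Zbp1 at least 3210-fold higher than the floor, and Igtp rose by 12.72±0.12 log2. Tap1 6.71±0.07, Socs1 6.48±0.23, Irf1 (929±14.7 against 14.5±1.8 CPM), Cxcl10 5.83±0.07, Cd274 4.74±0.09, B2m 4.14±0.05 (2641±88.1 against 150±2.73 CPM) and Ccl5 3.09±0.20 rose. Ttn -2.96±0.27, the receptor gene Kit -2.30±0.28, Relb -1.70±0.16, Mki67 -1.14±0.06, Tyr -0.81±0.08 and Mitf -0.61±0.05 fell. All measured members of the MHC class I list (16 of 16 (16)), the class II list (7 of 7 (7); adjusted p = 1.9e-04) and the list of GBP, IRG and other IFNg-inducible genes (22 of 22 (22)) rose. Cell death genes rose in 14 of 19 (14), with 1 lower (adjusted p = 1.2e-23), and T cell ligand genes in 6 of 6 (6). Proliferation genes fell in 20 of 25 (20), with 1 higher (adjusted p = 5.5e-04; adjusted p = 0.050 with an estimated correlation), and melanocyte genes in 12 of 17 (13), with 2 higher. 4444 genes were called (2344 higher, 2100 lower; 608 and 200 at least 2-fold). Psmb9 rose too (ratio 3459, counting interval 620 to 136700), but it overlaps Tap1 on chromosome 17 (34181987 to 34187764 and 34187553 to 34197225), and counts of near-identical genes such as Tgtp1 and Tgtp2 or the Gbp and H2 families leave the split among them uncertain.

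TNFa raised NF-kB targets and some chemokines in control B16 cells. Bcl3 was at least 20.6-fold higher than the floor, and Ccl5 3.50±0.19, Tnfrsf9 3.33±0.31, Casp4 2.78±0.27, Ddx58 2.35±0.12, Relb 2.09±0.11, Tapbp 2.07±0.06, Nfkbie 1.99±0.09, Cxcl10 1.95±0.08, the NF-kB inhibitor gene Nfkbia 1.53±0.12, B2m 1.40±0.05 and Ddit3 1.25±0.17 rose. Tyr -1.25±0.08, Mitf -0.94±0.06 and Trpm1 -0.86±0.06 fell, and Bmpr2 -2.80±0.27 and Ankfn1 -2.54±0.25 were among the largest falls. NF-kB targets rose in 10 of 17 (11), with 2 lower (adjusted p = 6.5e-15), MHC class I genes in 11 of 16 (12) and stress genes in 11 of 16 (11), with 1 lower (adjusted p = 3.9e-04), while melanocyte genes fell in 12 of 17 (12), with 2 higher (adjusted p = 2.7e-09). Antiviral genes rose in 10 of 25 (11), with 2 lower (adjusted p = 0.0047; adjusted p = 0.090 with an estimated correlation). 5591 genes were called (2897 higher, 2694 lower; 312 and 272 at least 2-fold). Fold changes fell with transcript length (Spearman rho = -0.495 across genes, which are not independent replicates), and 4888 genes were called with the length trend removed, 3921 in both, 3897 of these with the same sign.

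Given together, IFNb and IFNg raised Usp18 9.08±0.14, Isg15 8.34±0.19, Ifit1 7.39±0.11, Cxcl10 6.74±0.07, Tap1 6.67±0.07, Irf1 6.08±0.07, Stat2 5.55±0.09, Gsdmd 4.99±0.17, Cd274 4.99±0.09, B2m 4.52±0.05 and the stress gene Atf3 2.69±0.12, with Iigp1 at least 11970-fold and Zbp1 at least 3899-fold higher than the floor. Kit -3.01±0.34, Tyr -1.90±0.09, Mki67 -1.47±0.06, Bub1 -1.30±0.08 and Mitf -0.60±0.05 fell. Antiviral genes rose in 25 of 25 (25), cell death genes in 17 of 19 (17), with 1 lower (adjusted p = 1.4e-20), and proliferation genes fell in 23 of 25 (23), with 1 higher (adjusted p = 2.9e-07), as did melanocyte genes in 12 of 17 (12), with 1 higher (adjusted p = 1.5e-07). 7672 genes were called (4024 higher, 3648 lower; 1211 and 594 at least 2-fold). Fold changes fell with length across genes (rho = -0.342).

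IFNb with TNFa combined antiviral genes with NF-kB targets: Irf7 8.96±0.15, Usp18 7.94±0.16, Igtp 7.33±0.17, Cxcl10 4.66±0.07, H2-K1 4.47±0.10, Ccl5 3.92±0.18, B2m 3.45±0.05, Tap1 3.42±0.09, Casp4 3.18±0.25, Csf1 2.91±0.10, Postn 1.73±0.11 and Nfkbia 1.24±0.13 rose, and Bcl3 was at least 32.1-fold higher than the floor. Slc16a3 -2.52±0.22, Bnip3 -1.84±0.20, Egr1 -1.95±0.39, Trpm1 -1.03±0.06 and Pmel -0.96±0.04 fell. NF-kB targets rose in 13 of 17 (13, adjusted p = 8.9e-13) and chemokines in 5 of 7 (6, adjusted p = 2.9e-12), while melanocyte genes fell in 15 of 17 (15). 4518 genes were called (2533 higher, 1985 lower; 494 and 102 at least 2-fold), and Mki67 was not called (-0.03±0.06, adjusted p = 0.78) except with the length trend removed (-0.16). Fold changes rose with length across genes (rho = 0.253).

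IFNg with TNFa gave the most calls in control B16 cells: 8127 genes (4218 higher, 3909 lower; 1507 and 1080 at least 2-fold). The chemokine genes Cxcl9 (at least 6002-fold) and Cxcl11 (at least 1902-fold) were higher than the floor. Ccl5 9.94±0.10 (1658±67.8 against 1.67±0.247 CPM), Cxcl10 7.39±0.07, Cd74 9.45±0.26, Isg15 8.49±0.19, Casp4 6.35±0.16, Gsdmd 5.63±0.15, Lif 4.48±0.49, Atf3 3.93±0.11 and Nfkbia 1.89±0.12 rose. Kit -4.40±0.40, the collagen gene Col1a2 -3.88±0.22, Mki67 -3.38±0.07, Bub1 -3.03±0.10, Trpm1 -2.94±0.08, Tyr -2.73±0.09 and Mitf -1.46±0.06 fell. Proliferation genes fell in 25 of 25 (25, adjusted p = 2.6e-36) and melanocyte genes in 15 of 17 (15), with 1 higher, while NF-kB targets rose in 13 of 17 (13), with 2 lower (adjusted p = 8.5e-06) and stress genes in 11 of 16 (11), with 1 lower (adjusted p = 0.0013; adjusted p = 0.050 with an estimated correlation). Length and fold change were related across genes (rho = -0.235).

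Without cytokine, Ptpn2-null B16 cells differed from control cells in stress genes, among others. Egr1 1.38±0.23, the cystine transporter gene Slc7a11 1.22±0.11 (151±25.8 against 64.8±7.08 CPM, adjusted p = 1.3e-09), Trib3 1.10±0.12 (not called at 1.08 with only these groups in the fit), Chac1 1.04±0.14 (not called at 1.02 with only these groups in the fit), Slc6a9 0.95±0.12, Sesn2 0.89±0.10 and Mki67 0.26±0.06 (not called at 0.22 without control vehicle replicate 3 and 0.13 with the length trend removed) were higher, and Gbp3 -1.72±0.34 (not called at -1.29 without Ptpn2-null vehicle replicate 1), Clu -1.63±0.32, Sod3 -1.34±0.29 (not called at -1.11 without control vehicle replicate 3 and -1.17 without Ptpn2-null vehicle replicate 3) and Lgals9 -0.65±0.10 were lower (n = 3 per group). Stress genes were higher in 8 of 16 (10), with 2 lower (3, adjusted p = 6.3e-11). With only these groups in the fit 5 were called higher and 3 lower. The differences in Ifit1 (-0.64±0.26) and B2m (-0.03±0.05) were not called (adjusted p = 0.17 and 0.84). 360 genes were called (224 higher, 136 lower; 8 and 8 at least 2-fold), and the fold changes rose with transcript length across genes (rho = 0.448, and 314 called with that trend removed, 235 in both). Other settings gave 1357 with only these groups in the fit (710 higher, 647 lower), 1099 without the 5 libraries that stand apart (559 higher, 540 lower) and, with 1 library left out, 210, 228 and 181 (control vehicle replicates 1, 2 and 3), and 158 and 129 (Ptpn2-null vehicle replicates 2 and 3).

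Under IFNb, Ptpn2-null B16 cells held more of some transcripts that IFNg induces and of some MHC class I genes. Tgtp1 3.71±0.22, Gbp4 3.15±0.43, the immunoproteasome genes Psmb8 2.14±0.37 and Psmb9 1.75±0.24, Gbp9 1.96±0.29, H2-K1 1.45±0.08 (122±4.05 against 44.5±4.14 CPM, adjusted p = 1.4e-18), Zbp1 1.44±0.12, Nlrc5 0.77±0.15 (not called at 0.66 without control IFNb replicate 1), Tap1 0.67±0.06, B2m 0.43±0.05, Irf1 0.37±0.08 (not called at 0.31 without control IFNb replicate 1 and 0.32 without Ptpn2-null IFNb replicate 3) and Stat2 0.36±0.07 (not called at 0.31 without control IFNb replicate 1 and 0.31 without Ptpn2-null IFNb replicate 1) were higher. Capn6 -0.75±0.10, Postn -0.68±0.12 and Adamts1 -0.44±0.07 were lower, and Cxcl10 was not called (0.21±0.06, adjusted p = 0.22). MHC class I genes were higher in 10 of 16 (13, adjusted p = 1.5e-68), GBP, IRG and other IFNg-inducible genes in 11 of 22 (13) and antiviral genes in 8 of 25 (11), a count that was 1 to 5 when any 1 of the 6 libraries was left out. 65 genes were called (45 higher, 20 lower). The count was 156 with only these groups in the fit (81 higher, 75 lower), 104 without the 5 libraries that stand apart (66 higher, 38 lower) and, with 1 library left out, 35, 38 and 43 (control IFNb replicates 1, 2 and 3), and 43 and 41 (Ptpn2-null IFNb replicates 1 and 3).

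Under IFNg the genotypes of B16 differed in 4093 genes (2078 higher, 2015 lower; 377 and 170 at least 2-fold). Ptpn2-null cells held more of the stem cell antigen gene Ly6a 6.91±0.33 (11.41 without control IFNg replicate 2), Ifi205 5.92±0.23, the chemokines Cxcl9 3.92±0.11 (107±4.12 against 7.02±0.379 CPM, adjusted p = 3.0e-32), Cxcl11 3.80±0.20, Ccl5 1.84±0.10 and Cxcl10 1.44±0.05 (3246±14.3 against 1200±16.4 CPM), Tgm2 3.41±0.19, Fn1 3.01±0.09, Oas3 2.49±0.08, Casp4 2.33±0.10, Gbp5 1.93±0.07, Ifit1 1.23±0.07, Socs1 0.99±0.09, Cd274 0.71±0.06, Ripk1 0.65±0.06, Casp8 0.42±0.06 and B2m 0.29±0.04. Lower were Mgll -3.26±0.22, the melanocyte genes Trpm1 -2.56±0.08, Slc45a2 -1.92±0.06, Tyr -1.30±0.09 and Mitf -0.82±0.06, and Mki67 -0.85±0.07. Psmb9 was not called (0.14±0.07, adjusted p = 0.086), though it was with RLE size factors (0.16), the length trend removed (0.14), only these groups in the fit (0.15), or without the 5 libraries that stand apart (0.15) or Ptpn2-null IFNg replicate 3 (0.19). Antiviral genes were higher in 24 of 25 (24, adjusted p = 3.5e-52), NF-kB targets in 9 of 17 (9) and cell death genes in 14 of 19 (14), with 2 lower. Proliferation genes were lower in 23 of 25 (23, adjusted p = 1.2e-21) and melanocyte genes in 14 of 17 (14), with 1 higher. MHC class II genes were lower in 3 of 7 (4), with 1 higher.

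**Figure D2:**
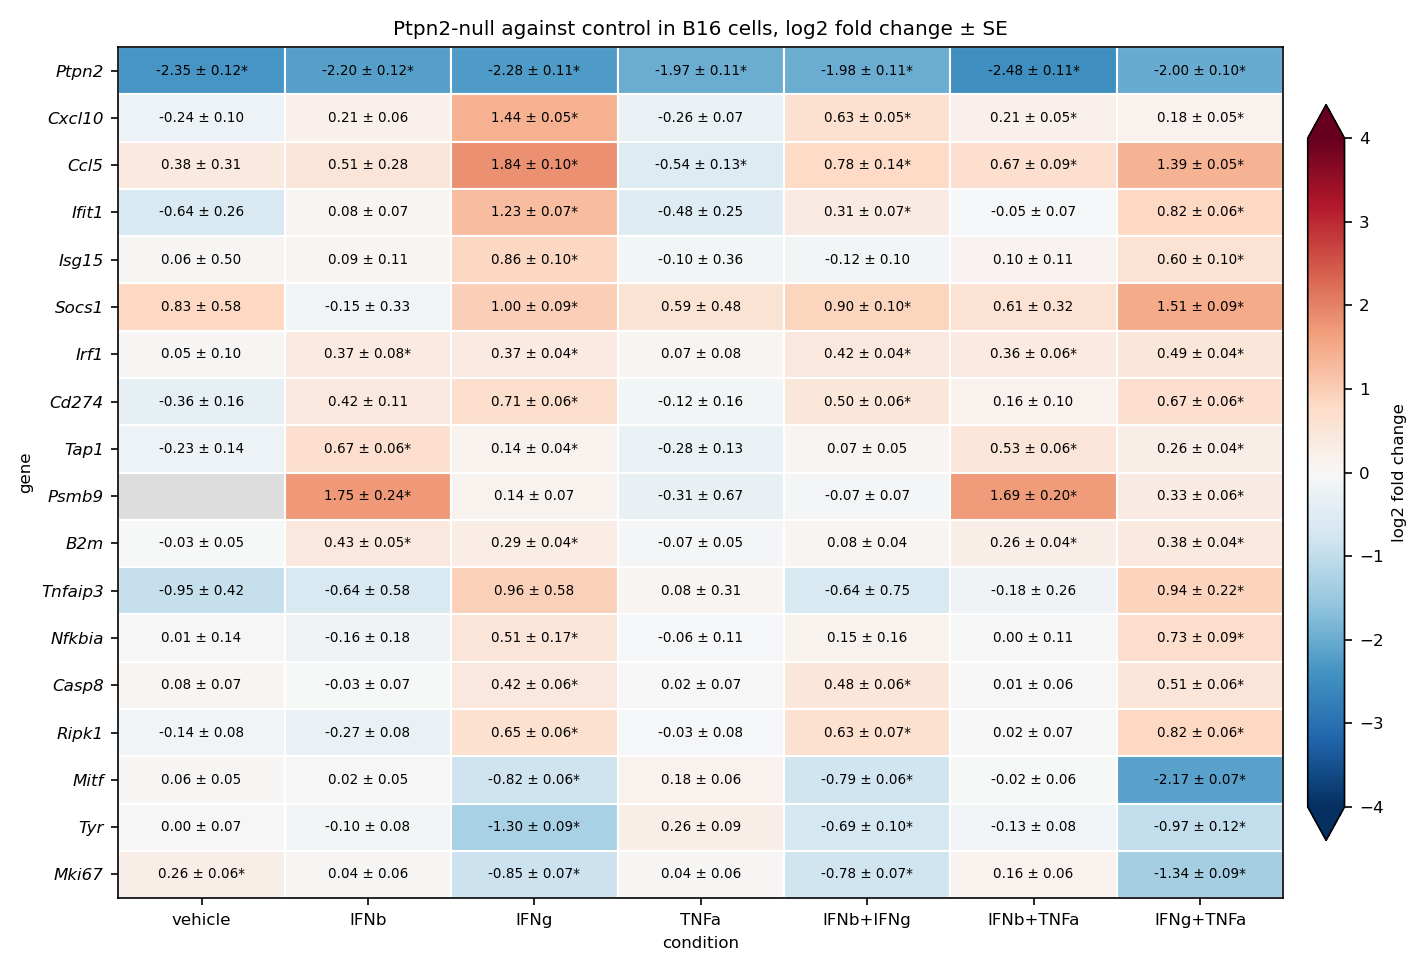
Log2 fold change ± SE of Ptpn2-null against control B16 cells for genes fixed in advance (vertical) under each treatment (horizontal), with colour saturating at 4, an asterisk for an adjusted p under 0.05 and grey where a group held 3 or fewer counts. Cxcl10 is 1.44±0.05 under IFNg and -0.24±0.10 under vehicle, and Mitf is lowest under IFNg with TNFa (-2.17±0.07).

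Under TNFa few genes separated the B16 genotypes. Id2 0.50±0.07 and the melanosome gene Pmel 0.22±0.04 were higher, and Clu -1.37±0.28 (not called at -1.13 without control TNFa replicate 2), Prkg2 -1.21±0.18, Capn6 -0.84±0.10, Postn -0.80±0.12 (15.9±1.69 against 27.9±2.55 CPM, adjusted p = 3.5e-05) and Cdkn1a -0.44±0.05 were lower. Nfkbia (-0.06±0.11), Tnfaip3 (0.08±0.31), Casp8 (0.02±0.07) and Ripk1 (-0.03±0.08) were not called. Melanocyte genes were higher in 2 of 17 (8, adjusted p = 2.9e-08). The count was 5 with no filter or without the 5 libraries that stand apart, and 1 without control TNFa replicate 2 or 3 or any of the 3 Ptpn2-null TNFa libraries. 110 genes were called (31 higher, 79 lower), with fold changes rising with length across genes (rho = 0.398). The count was 310 with no filter on low counts (193 higher, 117 lower) and, with 1 library left out, 70 and 56 (control TNFa replicates 1 and 2), and 36 and 60 (Ptpn2-null TNFa replicates 1 and 2).

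Under IFNb with IFNg, Ptpn2-null B16 cells held more Ly6a 4.12±0.14, Cxcl9 3.11±0.11, Ifi205 2.68±0.13, Cish 2.24±0.33, Cxcl11 2.14±0.15, Casp4 2.02±0.09, Gbp5 1.80±0.07, Socs3 1.37±0.09, Trib3 1.34±0.11, Cxcl10 0.63±0.05, Ripk1 0.63±0.07, Cd274 0.50±0.06, Casp8 0.48±0.06 and H2-K1 0.40±0.06. They held less Mgll -2.46±0.22, Egr1 -2.03±0.46, Trpm1 -1.72±0.09, Postn -1.22±0.13, Plk1 -1.04±0.07, Mki67 -0.79±0.07, Mitf -0.79±0.06 and Tyr -0.69±0.10 (-0.37 without the 5 libraries that stand apart). The proliferation list was lower in 24 of 25 (24, adjusted p = 8.1e-21) and melanocyte genes in 13 of 17 (13), with 1 higher. GBP, IRG and other IFNg-inducible genes were higher in 16 of 22 (16), with 1 lower. Genes of MHC class I presentation were higher in 9 of 16 (9), with 0 lower (1, adjusted p = 0.0036; adjusted p = 0.16 with an estimated correlation). 4504 genes were called (2247 higher, 2257 lower), and fold changes rose with length across genes (rho = 0.326). The count was 2164 with only these groups in the fit.

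Under IFNb with TNFa the called genes included IFNg-inducible and MHC class I genes. Tgtp1 2.62±0.17, Gbp4 2.25±0.30, Gbp9 2.07±0.22, Psmb9 1.69±0.20, Iigp1 1.68±0.12, Zbp1 1.06±0.09, H2-K1 0.89±0.07, Ccl5 0.67±0.09, Tap1 0.53±0.06, Irf1 0.36±0.06 and B2m 0.26±0.04 (not called at 0.23 with the length trend removed) were higher in Ptpn2-null cells, and Htra3 -1.52±0.24, Timp3 -1.20±0.19 and Postn -0.70±0.10 were lower. MHC class I genes were higher in 9 of 16 (12, adjusted p = 5.1e-45) and GBP, IRG and other IFNg-inducible genes in 11 of 22 (12). 70 genes were called (50 higher, 20 lower). Other settings gave 124 with only these groups in the fit (76 higher, 48 lower) and 135 without the 5 libraries that stand apart (84 higher, 51 lower).

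The most calls between B16 genotypes came under IFNg with TNFa, 4813 genes (2377 higher, 2436 lower; 371 and 470 at least 2-fold). Adam8 5.11±0.16, Crabp2 3.93±0.21, Ly6a 3.90±0.14, the death receptor gene Fas 3.62±0.30, Ccl2 3.32±0.25, Cxcl9 2.99±0.06 (8808±284 against 1108±38.9 CPM), Socs3 1.95±0.08, Socs1 1.51±0.09, Ccl5 1.39±0.05, Cxcl11 1.38±0.06, Tnfaip3 0.94±0.22, Ripk1 0.81±0.06, Nfkbia 0.73±0.09, Casp8 0.51±0.06 and Cd274 0.67±0.06 were higher in Ptpn2-null cells. Mgll -3.57±0.47, Tspan10 -3.45±0.09, Slc45a2 -2.62±0.07, the replication gene Cdc6 -2.33±0.17, Mitf -2.17±0.07 (56.9±5.83 against 257±14.6 CPM, adjusted p = 1.1e-32), Mki67 -1.34±0.09 and Tyr -0.97±0.12 were lower. NF-kB targets were higher in 14 of 17 (15, adjusted p = 4.3e-09), stress genes in 13 of 16 (14), with 1 lower and chemokines in 6 of 7 (6). Melanocyte genes were lower in 15 of 17 (15) and proliferation genes in 22 of 25 (23, adjusted p = 3.6e-27). GBP, IRG and other IFNg-inducible genes were split, higher in 11 of 22 (11), with 6 lower (7, adjusted p = 0.0071; adjusted p = 0.14 with an estimated correlation).

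Interactions asked whether the change from vehicle differed between genotypes. A positive value is a larger rise, or a smaller fall, in Ptpn2-null cells. For IFNg, Adam8 3.71±0.68, Crabp2 3.47±0.49, Fn1 3.17±0.14, Ifit1 1.86±0.27, Cxcl10 1.68±0.12 (adjusted p = 4.6e-17), Lgals9 1.49±0.11, Ccl5 1.46±0.34, Cd274 1.06±0.17 and Ripk1 0.78±0.10 were positive, and Mgll -2.75±0.27, Trpm1 -2.50±0.10, Tyr -1.30±0.12, Mki67 -1.11±0.09 and Mitf -0.88±0.08 were negative. Proliferation genes were lower in 20 of 25 (20, adjusted p = 4.5e-23) and melanocyte genes in 13 of 17 (14), with 1 higher, and antiviral genes were higher in 10 of 25 (11). 2516 genes were called (1064 higher, 1452 lower). For IFNg with TNFa, 3079 genes were called (1285 higher, 1794 lower), among them Adam8 6.34±0.67, Crabp2 4.80±0.52, Emp1 3.84±0.29, Lgals9 1.77±0.11, Cdc6 -2.33±0.19, Mitf -2.23±0.09, Tspan10 -3.47±0.11 and Kank4 -4.56±0.41. There, NF-kB targets were higher in 11 of 17 (11), with 1 lower and melanocyte genes lower in 13 of 17 (13, adjusted p = 2.2e-20). For IFNb with IFNg, Crabp2 3.19±0.48, Socs3 1.62±0.21, Cxcl10 0.87±0.11 and Cd274 0.85±0.17 were positive and Egr1 -3.41±0.51, Trpm1 -1.66±0.10 and Mki67 -1.05±0.09 negative. The proliferation list was lower in 23 of 25 (24). 1810 genes were called there (785 higher, 1025 lower). Other settings gave 1092 with only these groups in the fit and 3500 without the 5 libraries that stand apart (2127 higher, 1373 lower).

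Interactions with IFNb were positive for some MHC class I genes and negative for some stress genes. Slc7a11, Slc6a9, Trib3, Sesn2 and Gbp3 already differed the other way under vehicle, by a similar size (Trib3 1.105, Gbp3 -1.72). Their interactions, here and below for IFNb with TNFa and for TNFa, mostly carry that difference in the same vehicle libraries. They are not separate evidence of cytokine effects. Gbp3 1.75±0.34 (not called at 1.69 without control vehicle replicate 3 and 1.31 without Ptpn2-null vehicle replicate 1), H2-K1 1.22±0.18 (adjusted p = 6.1e-05), Tap1 0.90±0.16 (not called at 0.76 without control vehicle replicate 2), H2-D1 0.82±0.10 and B2m 0.46±0.07 (not called at 0.27 with the length trend removed) were positive, and Slc7a11 -1.39±0.17, Slc6a9 -1.14±0.19, Trib3 -1.04±0.20 (not called at -1.01 with only these groups in the fit) and Sesn2 -0.95±0.15 negative. Genes of MHC class I presentation were higher in 4 of 16 (8, adjusted p = 1.0e-12) and stress genes lower in 4 of 16 (5), with 0 higher (1). With only these groups in the fit the counts were 7, and 2 with 1 higher. 60 genes were called (22 higher, 38 lower), and fold changes fell with length across genes (rho = -0.439, and 56 called with that trend removed, 41 in both). The count was 115 with no filter on low counts (55 higher, 60 lower), 591 with only these groups in the fit (285 higher, 306 lower), 249 without the 5 libraries that stand apart (124 higher, 125 lower) and, with 1 library left out, 32 and 38 (control IFNb replicates 1 and 3), 32 and 38 (control vehicle replicates 1 and 3), 38 and 33 (Ptpn2-null IFNb replicates 1 and 3), and 35 and 31 (Ptpn2-null vehicle replicates 2 and 3). With IFNb and TNFa, Gbp3 1.86±0.34 (not called at 1.44 without Ptpn2-null vehicle replicate 1) and H2-D1 0.61±0.09 were positive and Slc7a11 -1.18±0.16 and Sesn2 -0.95±0.15 negative. MHC class I genes were higher in 4 of 16 (7, adjusted p = 4.5e-07). The count was 1 without Ptpn2-null vehicle replicate 1, and 2 without any other vehicle library, control IFNb with TNFa replicate 2 or Ptpn2-null IFNb with TNFa replicate 1. 107 genes were called (52 higher, 55 lower; rho with length = -0.431, and 87 called with that trend removed, 67 in both). Other settings gave 186 with no filter on low counts, 582 with only these groups in the fit (319 higher, 263 lower), 366 without the 5 libraries that stand apart (204 higher, 162 lower) and, with 1 library left out, 58 and 45 (control IFNb with TNFa replicates 2 and 3), 69 and 44 (control vehicle replicates 1 and 3), 54 and 59 (Ptpn2-null IFNb with TNFa replicates 1 and 2), and 65 and 33 (Ptpn2-null vehicle replicates 2 and 3). For TNFa alone, 4 genes were called, all lower: Slc6a9 -0.82±0.17 (adjusted p = 0.049), Cyr61 -0.61±0.10 (0.0054), Upf2 -0.48±0.10 (0.032) and Mthfd2 -0.40±0.07 (0.0095). None of these 4 stayed called in every fit: Cyr61 was lost only without Ptpn2-null TNFa replicate 1 (-0.57), and the other 3 without each of several libraries, Slc6a9 also with the replicate block. 583 genes had an unadjusted p under 0.05. The count was 2 with RLE size factors, 21 with no filter on low counts (6 higher, 15 lower), 2 with DESeq2, 1 with only these groups in the fit, 10 with the length trend removed, 7 without the 5 libraries that stand apart (1 higher, 6 lower) and, with 1 library left out, 1 and 2 (control vehicle replicates 1 and 2), 2 and 2 (control TNFa replicates 2 and 3), 15, 2 and 1 (Ptpn2-null vehicle replicates 1, 2 and 3), and 0 and 1 (Ptpn2-null TNFa replicates 1 and 3). In the stress list 0 of 16 (7) were lower (adjusted p = 4.8e-08), with 8 having an unadjusted p under 0.05 and 0 called by DESeq2. 5 were called with no filter, 4 without Ptpn2-null vehicle replicate 1, and 1 with the length trend removed or without the 5 libraries that stand apart.

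Non-additivity in control B16 cells was the log2 change under a pair of cytokines minus the sum of the changes under each. Libraries given TNFa, IFNb with IFNg, or IFNg with TNFa had lower slopes on transcript length than the others (below). Of the groups compared for IFNb and IFNg only the pair was among these, and for IFNb and TNFa only TNFa alone. A batch of those libraries would enter both contrasts in full and cannot be told apart from non-additivity there. IFNb and IFNg together gave less than that sum for interferon genes: Irf7 -7.63±0.20, Irgm2 -7.31±0.31, Usp18 -6.64±0.20, Isg15 -5.46±0.26, Ifit1 -4.67±0.15, Irf9 -4.17±0.13 (adjusted p = 5.1e-32), Tap1 -2.95±0.11, Lgals9 -2.61±0.09, B2m -2.34±0.07 and Cxcl10 -1.20±0.10. Bbc3 2.29±0.25, Gadd45a 1.86±0.24 and Cdkn1a 1.08±0.07 exceeded it. 5486 genes were called (2446 higher, 3040 lower; rho with length = -0.578, and 4412 called with that trend removed, 3446 in both, 3392 of these with the same sign), among the reported calls 24 of 25 (24) lower of the antiviral list and 15 of 16 (15) lower of the MHC class I list. For IFNb and TNFa, Bmpr2 2.80±0.33, Tyr 0.87±0.11, Mitf 0.66±0.08 and Cxcl10 0.59±0.10 exceeded the sum and Irf7 -2.56±0.45, Ddx58 -2.19±0.13 and B2m -0.68±0.07 (-0.39 with the length trend removed) fell short (3079 called, 1731 higher, 1348 lower; rho with length = 0.509, and 2508 called with that trend removed, 1901 in both). NF-kB targets were higher in 7 of 17 (7), with 1 lower, and in 4 with DESeq2 or without control vehicle replicate 3. For IFNg and TNFa, Ccl5 3.35±0.34 (adjusted p = 1.1e-11), C1s 2.43±0.21, Tnfaip3 2.42±0.56, Ifit2 1.97±0.14, Relb 1.38±0.19 and Nfkbia 1.22±0.19 exceeded the sum, while Hmgb2 -2.49±0.20, Col1a2 -2.46±0.31, Mki67 -2.21±0.09, Ccnb1 -2.21±0.14, Ddx58 -1.85±0.13, Tapbp -1.32±0.07 and B2m -0.63±0.07 fell short (3002 called, 1234 higher, 1768 lower). Proliferation genes fell short in 24 of 25 (24, adjusted p = 2.3e-110) and melanocyte genes in 14 of 17 (14), with 1 higher (2).

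Transcript length was measured in each B16 library as the slope of log2 CPM on log2 length. It was -0.272 to -0.012 in the 18 libraries given TNFa, IFNb with IFNg, or IFNg with TNFa, and 0.0287 to 0.153 in the other 24, so the libraries of these treatments were separate from the others. Within vehicle it was 0.129 to 0.148 in Ptpn2-null and 0.0456 to 0.0753 in control libraries. 5 libraries stood apart from both of their replicates (chi-square per degree of freedom above 3): control IFNb with IFNg replicate 2, control IFNb with TNFa replicate 1, Ptpn2-null IFNb with IFNg replicate 3, Ptpn2-null IFNg with TNFa replicate 1 and Ptpn2-null TNFa replicate 1. Length removal and leaving out these libraries were chosen after seeing the data.

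**Figure D3:**
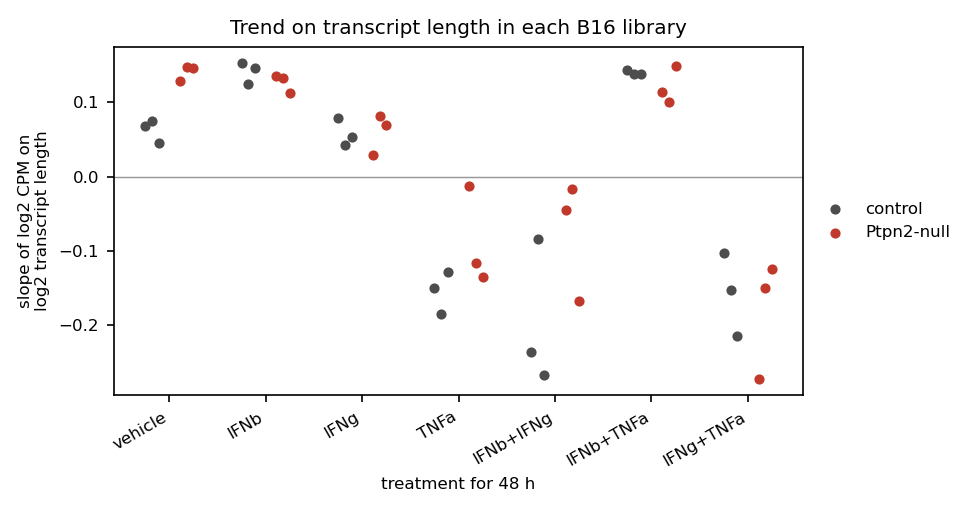
Slope of log2 CPM on log2 transcript length (vertical) in each B16 library (points), by treatment (horizontal) and genotype (colour). The libraries given TNFa, IFNb with IFNg, or IFNg with TNFa lie between -0.272 and -0.012 and all others above 0.

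IFNg raised antigen presentation and antiviral genes in control A549 lung cells. The tryptophan-degrading enzyme gene IDO1 was at least 931-fold, XAF1 at least 344-fold and GBP5 at least 48.2-fold higher than a floor of 3 counts, CD74 rose (ratio 409, counting interval 113 to 3385), and GBP1 7.65±0.20, HLA-B 5.07±0.07, IRF1 4.42±0.08, ISG15 4.37±0.15, CD274 4.11±0.32, PSMB9 4.02±0.10, TAP1 3.83±0.06, B2M 3.75±0.03, CHAC1 3.69±0.17 and IFIT1 1.75±0.14 rose (n = 2 per group). KRT4 -2.42±0.15 and MKI67 -0.63±0.03 fell. Genes of MHC class I presentation rose in 18 of 18 (18) and antiviral genes in 25 of 26 (25), and proliferation genes fell in 24 of 25 (24, adjusted p = 8.7e-08). 6272 of 13172 genes were called (3154 higher, 3118 lower). The count was 3954 with DESeq2. Without IFNg the Ptpn2-null A549 cells held more CDKN1A 0.57±0.06, APOL2 0.55±0.11 and HMOX1 0.35±0.04 and less MKI67 -0.28±0.03. Proliferation genes were lower in 4 of 25 (10). The count was 1 with DESeq2 or without control vehicle replicate 1 or Ptpn2-null vehicle replicate 2, and 2 without Ptpn2-null vehicle replicate 1. 388 genes were called (206 higher, 182 lower). Other settings gave 91 with DESeq2 (60 higher, 31 lower) and, with 1 library left out, 134 (control vehicle replicate 1), and 176 and 186 (Ptpn2-null vehicle replicates 1 and 2).

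Under IFNg the Ptpn2-null A549 cells held more of the acute phase gene FGB 4.31±0.10, the chemokines CXCL11 4.25±0.38, CCL2 3.25±0.16, CCL5 2.22±0.25 and CXCL10 (ratio 201, counting interval 35.8 to 7985), SOCS1 2.51±0.21, IDO1 2.30±0.04, the adhesion gene ICAM1 2.28±0.18, OASL 2.19±0.15, CD274 1.66±0.12 (41.8±1.31 against 13.2±0.67 CPM, adjusted p = 4.7e-38), CIITA 1.39±0.28 (not called at 1.39 with DESeq2), IFIT1 (64.8±1.85 against 32.5±0.719 CPM), IRF1 0.98±0.04, TNFAIP3 0.95±0.15, ISG15 0.93±0.07, TAP1 0.51±0.04, NFKBIA 0.47±0.07 and CASP8 0.42±0.07. KRT4 -1.96±0.30 and MKI67 -0.41±0.03 were lower. Antiviral genes were higher in 24 of 26 (24, adjusted p = 1.1e-45, or 0.00913 with an estimated correlation), GBP, IRG and other IFNg-inducible genes in 16 of 18 (17), chemokines in 5 of 8 (6) and cell death genes in 13 of 21 (14). The proliferation list was lower in 21 of 25 (22, adjusted p = 4.3e-18, or 0.0145 with an estimated correlation). 3197 genes were called (1708 higher, 1489 lower; 266 and 24 at least 2-fold). The count was 1438 with DESeq2. The interaction was positive for FGB 3.62±0.19, CCL2 3.12±0.25, SOCS1 2.53±0.73 (not called at 2.48 without control vehicle replicate 1 and 2.58 without control vehicle replicate 2), TNFAIP3 1.54±0.26, DDX58 1.44±0.15, WARS 1.08±0.05 and IRF1 0.96±0.15 and negative for TP63 -2.01±0.54 and KRT18 -0.51±0.04. 1486 genes were called (838 higher, 648 lower; 500 with DESeq2 (312 higher, 188 lower)), with antiviral genes higher in 13 of 26 (15) and proliferation genes lower in 14 of 25 (19).

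HT29 colon cells raised chemokines in response to IFNg: CXCL10 11.70±0.07 (5945±62.8 against 1.78±0.114 CPM), CXCL11 10.69±0.08, CXCL9 10.14±0.12 and CCL5 8.64±0.17 rose, HLA-DRA was at least 5347-fold, GBP5 at least 5026-fold, IDO1 at least 4593-fold and CIITA at least 1092-fold higher than the floor, and TAP1 7.61±0.07, IFIT1 5.80±0.06, CD274 5.49±0.10 and B2M (9177±66.4 against 574±2.69 CPM) rose (n = 2 per group). The stem cell gene LGR5 -3.96±0.19, the chloride channel gene CFTR -3.39±0.15 and MKI67 -0.36±0.04 fell. All measured MHC class II genes rose (11 of 11 (11)), as did NF-kB targets in 18 of 23 (18). 7463 genes were called (3865 higher, 3598 lower). Without IFNg, interferon-stimulated genes were already higher in Ptpn2-null HT29 cells: TRIM22 4.03±0.36, RSAD2 3.17±0.17, MX2 2.84±0.17, GBP4 2.82±0.16, OAS2 2.57±0.08 (87.2±5.5 against 14.7±0.134 CPM, adjusted p = 5.3e-33), CXCL10 2.57±0.21, PSMB9 2.38±0.32, IFIT1 1.74±0.07, TAP1 1.69±0.13, ISG15 1.40±0.06, CDKN1A 1.28±0.11 and B2M 0.78±0.04, while TNC -1.77±0.19 and MKI67 -0.22±0.04 were lower. Antiviral genes were higher in 25 of 26 (26) and MHC class I genes in 17 of 18 (17). Proliferation genes were lower in 14 of 25 (17), with 1 higher (2) and in 9 with DESeq2 (adjusted p = 5.2e-11; adjusted p = 0.13 with an estimated correlation). 2653 genes were called (1566 higher, 1087 lower; 218 and 10 at least 2-fold). Other settings gave 1268 with DESeq2 and, with 1 library left out, 1626 (control vehicle replicate 1), and 1746 (Ptpn2-null vehicle replicate 2).

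Under IFNg the Ptpn2-null HT29 cells held more of the cadherin gene CDH3 5.25±0.29, SOCS2 4.92±0.25, CLU 4.11±0.23, C3 3.64±0.06, CXCL9 2.88±0.04, SOCS3 2.89±0.08, TNFAIP3 1.13±0.09, SOCS1 1.02±0.08, CXCL10 (11860±28 against 5945±62.8 CPM), NFKBIA 0.67±0.06, CD274 0.47±0.05, RIPK1 0.32±0.06 and CASP8 0.25±0.06, with CCL2 at least 282-fold higher than the floor. ANXA10 -2.06±0.17, CCL5 -1.03±0.07, MKI67 -0.70±0.04 and ISG15 -0.36±0.04 were lower, and IFIT1 was not called (0.00±0.04, adjusted p = 0.95). The proliferation list was lower in 25 of 25 (25, adjusted p = 1.1e-32, or 0.0309 with an estimated correlation), NF-kB targets higher in 18 of 23 (18), with 2 lower and chemokines in 10 of 12 (10), with 1 lower. Antiviral genes were split, lower in 10 of 26 (10), with 9 higher, and their median and mean log2 fold change had opposite signs. 5258 genes were called (2679 higher, 2579 lower; 545 and 84 at least 2-fold; 3240 with DESeq2). Interactions were positive for CDH3 5.73±0.63 and RARRES1 3.46±0.12 and negative for TRIM22 -3.93±0.37, CCL5 -3.47±0.49, NLRC5 -3.39±0.41, RSAD2 -3.25±0.17, OAS2 -2.74±0.09, ISG15 -1.76±0.07, IFIT1 -1.74±0.08 and CXCL10 -1.57±0.23. Antiviral genes were lower in 24 of 26 (25) and MHC class I genes in 15 of 18 (16). 2403 genes were called (925 higher, 1478 lower; 1167 with DESeq2 (528 higher, 639 lower)).

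MelJuSo melanoma cells had the fewest calls for IFNg of the human lines, with 1412 genes called (776 higher, 636 lower; 787 with DESeq2; n = 3 per group). APOL4 was at least 220-fold higher than the floor, IDO1 rose (ratio 494, counting interval 136 to 4082), and BST2 6.71±0.24, GBP1 5.89±0.21, IRF1 4.89±0.10, TAP1 2.75±0.05, B2M 2.09±0.03, ISG15 1.59±0.14 and CD274 1.53±0.30 rose, while KCNN2 -1.50±0.32 fell and MKI67 was not called (0.00±0.03). MHC class I genes rose in 18 of 18 (18) and antiviral genes in 21 of 25 (23). Without IFNg, DMBT1 1.03±0.22 (not called at 0.85 without control vehicle replicate 3), S100B 0.43±0.05 and CDKN1A 0.24±0.04 were higher in Ptpn2-null cells and CDC6 -0.32±0.06 lower. Proliferation genes were lower in 8 of 25 (16, adjusted p = 3.5e-16, or 0.0192 with an estimated correlation), a count of 1 to 4 without control vehicle replicate 2 or 3 or any Ptpn2-null vehicle library. 201 genes were called (133 higher, 68 lower). The count was 311 with the replicate block (185 higher, 126 lower), 117 with DESeq2, 366 with only these groups in the fit (208 higher, 158 lower) and, with 1 library left out, 115, 128 and 98 (control vehicle replicates 1, 2 and 3), and 97 and 114 (Ptpn2-null vehicle replicates 2 and 3).

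Under IFNg the genotypes of MelJuSo differed in 6278 genes (3129 higher, 3149 lower; 359 and 137 at least 2-fold). TRIM22 5.10±0.22, GBP5 5.07±0.28, OASL 4.83±0.39, the protease gene CTSS 4.67±0.14, CAND2 4.46±0.15, IDO1 4.33±0.05, CD274 2.45±0.16 (22.5±3.46 against 4.04±1.03 CPM, adjusted p = 7.6e-27), SOCS1 1.68±0.25, SOCS3 1.65±0.04, IFIT1 1.30±0.14, CIITA 1.23±0.04, IRF1 0.89±0.05, TAP1 0.78±0.04, NFKBIA 0.59±0.10 and CASP8 0.29±0.08 were higher in Ptpn2-null cells, CXCL11 at least 27.7-fold above the floor, and CXCL9 (ratio 138, counting interval 24.4 to 5492) and CXCL10 (ratio 45, counting interval 15.1 to 221) as well. Lower were the sterol genes DHCR7 -2.75±0.36 and INSIG1 -2.23±0.05, the melanocyte genes DCT -1.88±0.05 and MITF -1.13±0.04, TNFAIP3 -1.51±0.07 and MKI67 -0.69±0.04. Antiviral genes were higher in 23 of 25 (23, adjusted p = 9.4e-33) and MHC class II genes in 9 of 10 (9), and melanocyte genes were lower in 15 of 17 (15), with 2 higher (adjusted p = 2.0e-10). Chemokines were higher in 5 of 6 (5, adjusted p = 0.0030; adjusted p = 0.058 with an estimated correlation). Interactions were positive for CAND2 4.80±0.62, CMPK2 3.37±0.73, CD274 2.44±0.44, ASNS 1.72±0.07, IFIT1 1.12±0.28 and CIITA 1.09±0.08 and negative for INSIG1 -2.10±0.06, DCT -1.68±0.07, TNFAIP3 -1.51±0.10, MITF -1.14±0.05 and MKI67 -0.56±0.05 (4351 called, 2041 higher, 2310 lower). Antiviral genes were higher in 19 of 25 (21) and melanocyte genes lower in 15 of 17 (15), with 1 higher.

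**Figure D4:**
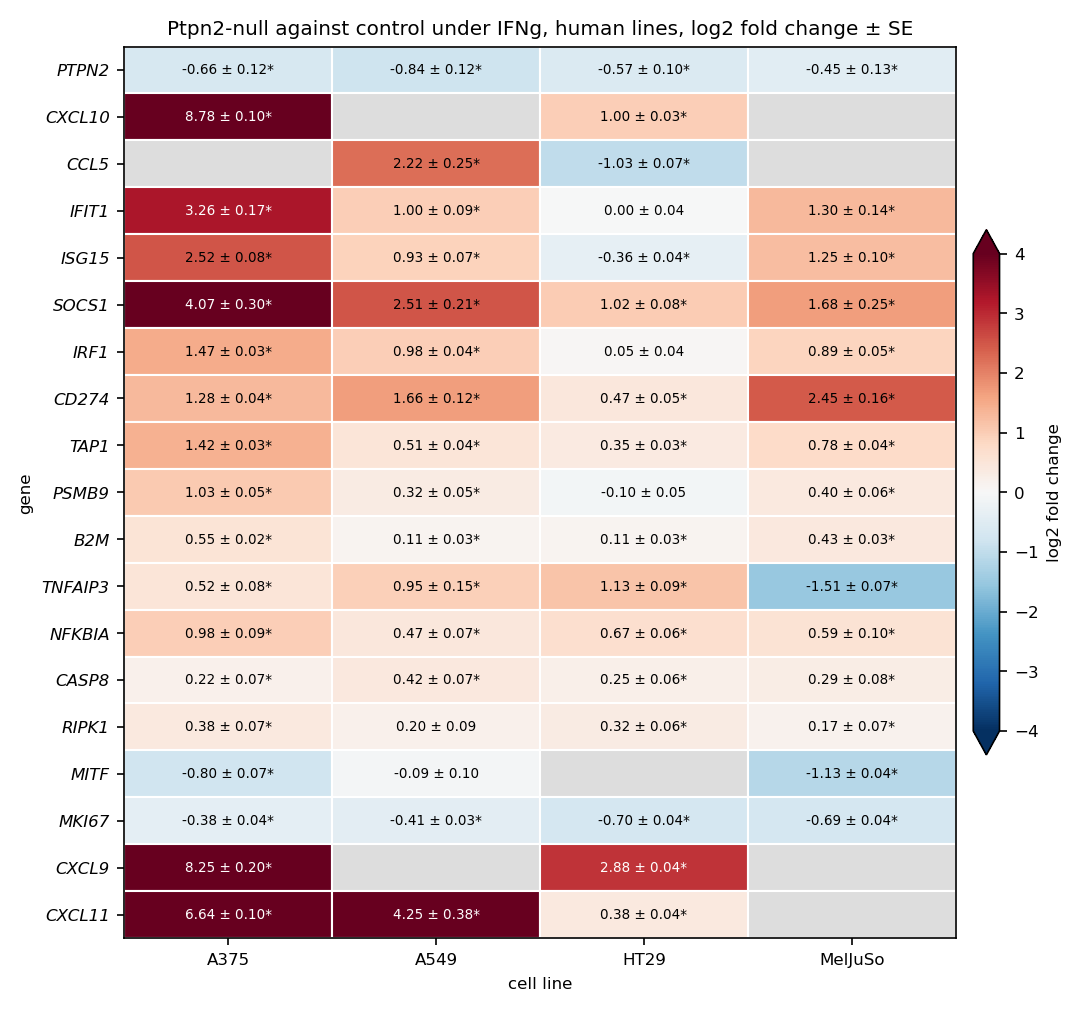
Log2 fold change ± SE of Ptpn2-null against control under IFNg for genes fixed in advance (vertical) in each human line (horizontal), as labelled, with colour saturating at 4, an asterisk for an adjusted p under 0.05 and grey where a gene was not tested or a group held 3 or fewer counts. CD274 is higher in all 4 lines (1.28±0.04 in A375, 0.47±0.05 in HT29, 1.66±0.12 in A549 and 2.45±0.16 in MelJuSo), while TNFAIP3 is lower in MelJuSo (-1.51±0.07) and higher in A549 (0.95±0.15) and HT29 (1.13±0.09).

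A375 values are given by label, and every comparison with its vehicle libraries carries the reversed PTPN2 levels of those libraries. Against the vehicle libraries labelled control, the IFNg libraries labelled control held more GBP5 (ratio 807, counting interval 145 to 31900), CIITA 6.13±0.16, GBP1 5.22±0.07, WARS 4.53±0.03, IRF1 4.23±0.07, HLA-B 3.59±0.05, TAP1 3.19±0.07, B2M 2.11±0.03 and CD274 1.11±0.06, with IDO1 at least 89.8-fold higher than the floor, and less ARHGDIB -4.25±0.17, ALDOC -3.46±0.09, MITF -1.55±0.05, IFIT1 -1.28±0.26 and MKI67 -1.05±0.04. Genes of MHC class I presentation were higher in 17 of 18 (17) and proliferation genes lower in 23 of 25 (23), with 1 higher. Antiviral genes were higher in 11 of 26 (11), with 6 lower (adjusted p = 0.037; adjusted p = 0.10 with an estimated correlation). 8848 genes were called (4424 higher, 4424 lower). Under vehicle the libraries labelled Ptpn2-null held more FLRT1 2.76±0.53, MYCL1 2.53±0.37, C5AR1 2.08±0.18, TRIB3 1.28±0.03, WARS 0.89±0.04, IRF1 0.68±0.11 and CD274 0.46±0.06 than those labelled control, and less TRIM22 -2.00±0.22, C3 -1.56±0.10, CDKN1A -1.46±0.04, HSPA1A -1.46±0.17 and MITF -0.34±0.05. Stress genes were higher in 11 of 17 (11), with 4 lower (5) and proliferation genes in 10 of 25 (11), with 2 lower (adjusted p = 0.0072; adjusted p = 0.058 with an estimated correlation). 2831 genes were called (1660 higher, 1171 lower). Other settings gave 1518 with DESeq2 (1006 higher, 512 lower) and, with 1 library left out, 1785 and 1763 (labelled control vehicle replicates 2 and 3).

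Under IFNg, where the PTPN2 levels followed the labels, Ptpn2-null A375 cells held more CXCL10 8.78±0.10 (334±9.37 against 0.721±0.368 CPM, adjusted p = 8.4e-157), CXCL9 8.25±0.20, CXCL11 6.64±0.10, A2M 5.46±0.26, IDO1 4.99±0.05, SOCS1 4.07±0.30, IFIT1 3.26±0.17, CTSS 3.25±0.05, ISG15 2.52±0.08, ICAM1 2.19±0.03, CIITA 1.82±0.04, IRF1 1.47±0.03, TAP1 1.43±0.03, CD274 1.28±0.04, NFKBIA 0.98±0.09, B2M 0.55±0.02, RIPK1 0.38±0.07 and CASP8 0.22±0.07 (not called at 0.21 with DESeq2 and 0.16 without control IFNg replicate 1). NLRP10 -2.35±0.30, CCNA1 -1.85±0.15, KIF26B -1.81±0.17, MITF -0.80±0.07 and MKI67 -0.38±0.04 were lower (n = 3 per group). All measured MHC class I genes (18 of 18 (18); adjusted p = 1.5e-40) and MHC class II genes (11 of 11 (11)) were higher, as were antiviral genes in 25 of 26 (25), T cell ligand genes in 8 of 9 (8), with 1 lower and NF-kB targets in 15 of 20 (15), with 1 lower. The proliferation list was lower in 16 of 25 (17), with 4 higher. 6817 genes were called (3463 higher, 3354 lower; 766 and 90 at least 2-fold). The interaction, by label, was positive for SECTM1 5.23±0.26, TRIM22 5.21±0.23, GBP4 4.82±0.48, IFIT1 3.95±0.31, CDKN1A 2.69±0.06, ISG15 2.52±0.24, ICAM1 2.45±0.08 and TAP1 1.73±0.12 and negative for INHBE -2.84±0.20, TRIB3 -1.77±0.04 and MKI67 -0.41±0.06 (6314 called, 3093 higher, 3221 lower).

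Genotype effects under IFNg were then compared among the 4 human lines in a single model. 8500 of 15322 genes differed, including all 18 measured MHC class I genes (18), 11 of 11 MHC class II (11), 10 of 12 chemokines (10), 26 of 26 antiviral genes (26), 17 of 18 GBP, IRG and other IFNg-inducible genes (17), 20 of 22 JAK-STAT genes (21), 21 of 24 NF-kB targets (22), 18 of 23 cell death genes (18), 8 of 9 T cell ligand genes (8), 23 of 25 proliferation genes (23), 10 of 17 melanocyte genes (10) and 16 of 17 stress genes (17). Leukocyte markers differed in 3 of 6 (3), fibroblast markers in 3 of 7 (3), epithelial markers in 4 of 10 (4) and colon epithelial markers in 1 of 6 (1). The test compares only the IFNg groups, in which the A375 PTPN2 levels followed the labels. Filter, scaling and spread came from all 39 human libraries, vehicle included.

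Marker lists for other cell types were measured in every library. Epithelial markers summed to 8054 to 8644 CPM in HT29 and 3421 to 4388 CPM in A549, against 253 to 548 CPM in A375, 5.09 to 9.7 CPM in MelJuSo and at most 2.62 CPM in B16. Colon epithelial markers reached 573 to 687 CPM in HT29 and 12.9 to 36.7 CPM in A549. HT29 control IFNg replicate 1, whose cell type label names the lung, held 659 CPM of colon markers, like its replicate (687 CPM). Fibroblast markers summed to 27.5 to 104 CPM in B16, 23.1 to 66.8 in MelJuSo, 8.44 to 45 in A375, 4.97 to 13.2 in A549 and 0.92 to 6.54 in HT29. Leukocyte markers summed to 1854 to 3290 CPM in HT29, 123 to 209 in A375, 102 to 170 in MelJuSo, 30.3 to 79 in A549 and 1.87 to 18.7 in B16. Several sums differed at least 1.5-fold, in group means and without overlap of libraries, between compared groups. From vehicle to IFNg in cells labelled control, A375 fibroblast markers went from 41.4 and 43 to 8.44 to 10.8 CPM, its epithelial markers from 455 and 467 to 253 to 268, its leukocyte markers from 190 and 194 to 123 to 128, HT29 fibroblast markers from 1.02 and 1.73 to 2.62 and 2.93, A549 colon epithelial markers from 31 and 31.2 to 16.4 and 19.6, and MelJuSo epithelial markers from 7.78 to 9.7 to 5.69 to 6.08. In B16 control cells leukocyte markers were 2.62 to 2.98 CPM under vehicle, 5.35 to 6.79 under IFNg, 7.15 to 7.9 under TNFa, 6.83 to 12.5 under IFNb with IFNg, 5.23 to 6.8 under IFNb with TNFa and 16.1 to 18.7 under IFNg with TNFa. Between genotypes under IFNg (control, then Ptpn2-null), fibroblast markers were 50.8 to 53.5 and 23.1 to 30.5 CPM in MelJuSo, 8.44 to 10.8 and 19.6 to 23.3 in A375 and 2.62 and 2.93 and 5.73 and 6.54 in HT29, and leukocyte markers 123 to 128 and 191 to 209 in A375 and 41.5 and 43.7 and 69.7 and 79 in A549. B16 fibroblast markers were 59.3 to 66.4 and 38.4 to 42.7 CPM under IFNb with IFNg, and 53.6 to 60.3 and 27.5 to 34.6 under IFNg with TNFa. Epithelial and colon epithelial markers of B16 also differed in some comparisons, at no more than 8.78 CPM. Whether these changes arose within the cells was not tested. All sums were taken without TMM scaling. After TMM scaling LYZ alone had group means of 2021 to 2887 CPM in HT29.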

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

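The A375 tests, the mean slope and batch tests of length, and the IFNB1 test below were chosen after the result was seen.

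Genotype effects differed between vehicle and cytokine by the interaction test in B16: 60 genes for IFNb, 2516 for IFNg, 4 for TNFa, 1810 for IFNb with IFNg, 107 for IFNb with TNFa and 3079 for IFNg with TNFa. The same test with IFNg called 6314 genes in A375 (by label), 1486 in A549, 2403 in HT29 and 4351 in MelJuSo, and 8500 genes differed among the 4 human lines in their genotype effect under IFNg. These were singled out because the effects differed between conditions or lines. In splits that redrew the groups within strata (21 splits per test, the real one included), 1 split, the real one, reached the count for IFNg (2516, highest other 2238), IFNb with TNFa (107, highest other 81), IFNg with TNFa (3079, highest other 2813) and MelJuSo (4351, highest other 4202). More splits reached it for IFNb (2 splits, 60 against 78), TNFa (4 splits, 4 against 29) and IFNb with IFNg (4 splits, 1810 against 1945). A split could redraw the genotypes under 1 treatment and leave them as they were under the other, which keeps that genotype effect in the count. The outcome depends on which splits were drawn, so these tests cannot decide whether the interaction counts arose by chance. The median of the other splits was 0 genes in each of these tests. Mixed groups put any real difference into the spread within groups, which lowers such counts. Every B16 interaction shares its vehicle libraries with the others.

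PTPN2 was higher in A375 vehicle libraries labelled Ptpn2-null (24.1 to 25.1 CPM) than in those labelled control (11.9 and 12.1 CPM), the reverse of what the labels name. Of genes called between genotypes under IFNg that moved little with IFNg itself, 31.1% of 2836 kept the sign of their genotype effect under vehicle in A375, against 62.9% of 1468 in A549, 80.1% of 1790 in HT29 and 58% of 4135 in MelJuSo; among genes called under both treatments the share was 16.8% of 849 in A375, 86% of 100 in A549, 91.9% of 590 in HT29 and 80.9% of 110 in MelJuSo. The correlation of the effects under IFNg and vehicle across the first set of genes, which are not independent replicates, was -0.499 in A375 and 0.365, 0.574 and 0.264 in the other lines, in that order. These shares fit exchanged genotype labels of the A375 vehicle groups, as a hypothesis found and tested on the same data, but not every gene turned: by label, IRF1 (0.68 under vehicle, 1.47 under IFNg), CD274 (0.46, 1.28) and MITF (-0.34, -0.80), which respond to IFNg and are outside these shares, kept their sign, which runs against an exchange if their genotype effect has the same sign under both treatments. By label, MHC class I genes had 0 of 18 higher and 5 lower under vehicle, against 18 and 0 under IFNg. MHC class II genes had 0 of 11 higher and 4 lower, against 11 and 0. Antiviral genes had 1 of 26 higher and 4 lower, against 25 and 0. GBP, IRG and other IFNg-inducible genes were split under vehicle, 5 of 17 higher and 5 lower, against 17 and 0. Genes that respond to IFNg thus went both ways. The exchange is therefore not settled, and correct labels with genotype effects that turn with IFNg in many genes stay open and untested. An IFNg-dependent change of PTPN2 mRNA alone with correct labels is argued against, since other genes turned with it (31.1% against at least 58% elsewhere). No library was regrouped.

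Long transcripts were lower in the 18 B16 libraries given TNFa, IFNb with IFNg, or IFNg with TNFa (slopes of -0.272 to -0.012 per log2 length, against 0.0287 to 0.153 in the other 24; 10606 of 11726 tested genes had a length). The trend as the whole cause of the TNFa calls is argued against: 4888 of 11726 genes were called with it removed (5591 before), 3921 in both, 3897 of these with the same sign. In control cells given IFNb with TNFa the mean slope was 0.14 (0.0632 under vehicle, -0.154 under TNFa), within the 0.125 to 0.153 of IFNb alone. With IFNg, slopes were 0.0431 to 0.0794 alone and -0.214 to -0.102 with TNFa. An effect of TNFa itself that IFNb hides cannot be told apart here, so it stays open. A library batch that holds these 3 treatments could give the pattern: the highest of the 18 slopes was -0.012, below the other 24, and as the labels name no batch, batch and treatment cannot be told apart. A biological effect of these treatments on long transcripts also stays open and untested.

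Interferon-stimulated genes were higher in HT29 vehicle libraries of Ptpn2-null cells. Carry-over from IFNg-treated HT29 libraries is argued against: the rise was a median 4.84% of the IFNg level over 26 antiviral genes and 0.0706% over the 20 genes that IFNg raised most, a ratio of 68.5, and HLA-DRA stood at 0 CPM. Type I interferon made by the cells may contribute but was not settled: IFNB1 had 5 and 1 counts in the Ptpn2-null and 0 and 0 in the control vehicle libraries, and the lowest, 1 count, is under the floor of 3. That floor was added to the IFNB1 test after its value was seen. In the IFNg-treated HT29 libraries IFNB1 had 139 and 138 counts in control and 152 and 90 in Ptpn2-null cells.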

How the results depend on the processing

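The removal of the length trend and the fit without the 5 B16 libraries that stand apart were chosen after the data were seen; all other alternatives were planned. Counts are genes with an adjusted p under 0.05 by edgeR unless DESeq2 is named, and a count not given here stayed within 1.5 times the reported one.

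RLE size factors moved 1 count, the interaction with TNFa (4 to 2); it shifted the median of all genes by at most 0.0354 (log2), and the share of higher genes moved by under 10 percentage points in every comparison with RLE. With no filter, the B16 genotype effect under TNFa went from 110 to 310, and the interactions from 60 to 115 for IFNb, 4 to 21 for TNFa and 107 to 186 for IFNb with TNFa. With DESeq2 the interaction with TNFa gave 2 genes. In the human lines DESeq2 gave 1518 instead of 2831 for A375 under vehicle, 3954 instead of 6272 for the A549 response, 91 instead of 388, 1438 instead of 3197 and 500 instead of 1486 for its genotype effects under vehicle and IFNg and its interaction, 1268 instead of 2653, 3240 instead of 5258 and 1167 instead of 2403 for the same 3 results in HT29, and 787 instead of 1412 and 117 instead of 201 for the MelJuSo response and its genotype effect under vehicle.

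With only the compared groups in the fit, B16 genotype effects went from 360 to 1357 under vehicle, 65 to 156 under IFNb, 4504 to 2164 under IFNb with IFNg and 70 to 124 under IFNb with TNFa. The interactions went from 60 to 591 for IFNb, 4 to 1 for TNFa, 1810 to 1092 for IFNb with IFNg and 107 to 582 for IFNb with TNFa, and the MelJuSo vehicle effect from 201 to 366. Without the 5 libraries that stand apart, B16 genotype effects were 1099 under vehicle, 104 under IFNb and 135 under IFNb with TNFa, and the interactions 249 for IFNb, 7 for TNFa, 3500 for IFNb with IFNg and 366 for IFNb with TNFa. In both, the spread is estimated from other libraries. Chi-square per degree of freedom between replicates was 1.268 to 1.779 in the vehicle groups. It reached 6.866 in control and 5.837 in Ptpn2-null libraries given IFNb with IFNg. A spread shared over all groups tends to be too wide for the vehicle contrast and too narrow for IFNb with IFNg, so its 4504 calls may be too many. Whether this explains all these moves was not tested. With the length trend removed, the interaction with TNFa gave 10 genes and no other count moved beyond 1.5 times. Which genes were called changed more in some comparisons. The share of calls that stayed was 61.7% for non-additivity of IFNb and TNFa and 62.6% for the interaction with IFNb and TNFa. It was 65.3% for the vehicle genotype effect and 70.1% for the TNFa response, against 99.1% for the genotype effect under IFNg.

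Leaving out each library in turn (81 fits within lines, 20 for the difference among human lines) gave these ranges where a count moved beyond 1.5 times: 1763 to 2488 for A375 under vehicle as labelled (2831 with all), 134 to 344 for A549 (388), 1626 to 1918 for HT29 (2653) and 97 to 138 for MelJuSo (201) under vehicle; 129 to 267 under vehicle (360), 35 to 51 under IFNb (65) and 36 to 128 under TNFa (110) for the B16 genotype effects; and 31 to 74 for IFNb (60), 0 to 15 for TNFa (4) and 33 to 114 for IFNb with TNFa (107) for the B16 interactions. Where this left a group with 1 library, that library is assumed to vary like the other groups. The cause of these moves was not tested.

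The replicate block moved 1 count, the MelJuSo genotype effect under vehicle (201 to 311), and among named genes it ended 1 call, Slc6a9 in the TNFa interaction (-0.82 with and without the block). It changed no other call of a named gene and no other count by more than 1.5 times. The labels give the libraries only a shared number. The mean correlation of same-numbered libraries' deviations from their group means was -0.003 in B16, 0.00633 in A375, 0.0372 in A549, 0.0703 in HT29 and 0.0623 in MelJuSo, and 15 of 42, 7 of 11, 8 of 8, 8 of 8 and 11 of 12 libraries correlated best with their own number. With 2 libraries per group in A549 and HT29, deviations within a group mirror each other, so these 8 are not independent.

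Of 530 values of named genes that were called, none changed sign in any alternative that gave it a value. 11 lost their call in at least 1 alternative fit and 17 without at least 1 library, 23 in all. Genes left out of the text for this reason are not among them. Many genes were named because they were called with large changes in the same data, which favours a stable sign. Depth was 3498860 to 9605776 counts per library, which leaves genes near the floor with bounds or counting intervals in place of fold changes, and leaves interactions of such genes out.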

Other observations

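Some genes outside the lists were among the largest genotype differences under IFNg: Ly6a, Tgm2 and Fn1 in B16, FGB in A549, CDH3 and CLU in HT29, A2M in A375, and the sterol genes DHCR7 and INSIG1, which were lower, in MelJuSo. Their values are in the comparisons above, and no explanation was tested.

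Splits of 3 against 3 libraries (10 splits, the real one included) are too few for a share under 0.05. The real counts and the highest of the other splits, with 1 split reaching the real count in each, were 3578 and 0 for the IFNb response in B16 control cells, 4444 and 1 for IFNg, 5591 and 0 for TNFa, 7672 and 160 for IFNb with IFNg, 4518 and 2 for IFNb with TNFa, and 8127 and 0 for IFNg with TNFa. For the genotype contrast in B16 they were 360 and 0 under vehicle, 65 and 0 under IFNb, 4093 and 0 under IFNg, 110 and 0 under TNFa, 4504 and 3600 under IFNb with IFNg, 70 and 0 under IFNb with TNFa, and 4813 and 282 under IFNg with TNFa. In the human lines they were 6817 and 0 for A375 under IFNg, 1412 and 0 for the MelJuSo response, 201 and 0 for MelJuSo under vehicle and 6278 and 0 for MelJuSo under IFNg. The 3600 genes of another split under IFNb with IFNg point to a structure of those 6 libraries, of which control replicate 2 and Ptpn2-null replicate 3 stood apart from their replicates. For non-additivity, splits within strata (21 each) reached the real count once for IFNb with IFNg (5486, highest other 4481). They reached it 4 times for IFNb with TNFa (3079 against 4166) and for IFNg with TNFa (3002 against 4085). These splits could likewise leave 1 stratum as it was, so they cannot decide about chance. The median of the other splits was 0 in each of the comparisons above. Mixing the libraries of the groups puts any real difference into the spread within groups, which lowers the count. Low counts in the other splits are therefore no evidence against chance by themselves.

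A hypothesis written before its test was that Ptpn2 loss acts as a stronger IFNg response. The slope of the genotype effect under IFNg on the IFNg response, from different control IFNg libraries, was 0.178 in B16, 0.0991 in A549, 0.105 in HT29 and 0.4 in MelJuSo (correlation 0.414, 0.191, 0.273 and 0.27 across genes, which are not independent replicates). Of genes that moved at least 2-fold with IFNg, 89.9%, 64.2%, 72% and 96.7% had a genotype effect of the same sign. The lowest slope, 0.0991, is above 0, as the hypothesis predicted for a trend over all genes in levels under IFNg, but not every class of induced genes followed it. The slope does not subtract the vehicle difference, so it does not measure the size of the rise. With a single guide per genotype, it also cannot tell Ptpn2 loss from other differences between the cells carrying each guide. By the interaction, the rise in Ptpn2-null HT29 cells was smaller for 24 of 26 antiviral genes (median -1.623) and 15 of 18 MHC class I genes, and larger for none. It was larger for 13 of 26 antiviral genes in A549 and 19 of 25 in MelJuSo, and smaller for none. In HT29, 26 of 26 antiviral genes rose with IFNg (median log2 fold change 5.34), while under IFNg 10 were lower and 9 higher in Ptpn2-null cells (median -0.006), and of 11 MHC class II genes, which all rose, 4 were higher and 2 lower. In B16 all 7 measured MHC class II genes rose with IFNg, while 3 were lower and 1 higher in Ptpn2-null cells. A375 was left out because of its vehicle labels.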
